A study of Homo sapiens with 4 samples.

How the data were processed

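RNA from 4 samples of A2058 cells, a human melanoma line, was measured on 2 two-colour Agilent arrays. Cells had been transfected with siRNA against PARP1 or with a control siRNA and were collected at 48 h or 72 h. These times follow the sample titles; a separate time field of the labels names day 4 and day 5, and the difference was not resolved. RNA was extracted with TRIzol and labelled after linear amplification, per the labels' protocols. Each array held both siRNAs of one time, with PARP1 siRNA in Cy5 (red) and control siRNA in Cy3 (green). The dyes were not swapped, so dye and siRNA could not be separated. Each of the 4 groups had 1 sample. Both arrays lay on the same slide.

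Spots had been quantified with Agilent Feature Extraction 11.5.1.1 under protocol GE2_1105_Oct12, per the file headers. The submitters' processing notes name version 13. The deposited scanner files gave, per spot and channel, the median intensity and the median local background intensity without correction. They also gave processed intensities, background-subtracted and dye-normalized per the file headers, and a log10 ratio of red over green, per the file headers. Flags for spots well above background, saturated or outlying were also deposited. The authors' deposited values held a linear intensity for each probe and sample. The steps behind them were not stated in the sources used here. The column medians were 127.1 for PARP1 siRNA and 127.6 for control siRNA at 48 h, and 129.7 and 130.01 at 72 h. On the log2 scale each column correlated at 0.9997 or 0.9998 with the processed signal of its own channel. At least 95.4% of the values in each column lay within 0.1 log2 units of that signal, so scale and direction were settled from the scanner values.

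Each array carried 180880 spots, of which 4974 were controls. The other 175906 spots belonged to 75149 probes, 49541 with 2 spots and 25608 with 3. In the median signals of probe spots, PARP1 siRNA gave 93 and control siRNA 86 at 48 h, and 123 and 112 at 72 h, over median local backgrounds of 25, 26, 26 and 30. Outlier flags for non-uniformity or population, in either channel, covered 8.80% of probe spots on the 48 h array and 8.17% on the 72 h array. No spot was saturated. The number of arrays limited the precision. The SD between spots of one probe within an array was 0.12 log2 units on both arrays, and it covers measurement error alone.

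Background was corrected with normexp at an offset of 50, and each array was normalized by loess, in limma 3.58.1 under R 4.3.3 with the data.table package (1.17.8). Control and outlier-flagged spots had weight 0 in the loess. Outlier-flagged spots were then left out, and the other spots of a probe were averaged. The log2 ratio was PARP1 siRNA over control siRNA. A probe counted as measured where at least 0.5 of its unflagged spots were well above background in 1 or both channels on each array, which held for 49238 probes. A further 5418 probes had all spots flagged on an array. Levels of single channels for comparisons between times were taken after Aquantile normalization between arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

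At a single time there was no test, and probes at or past 2-fold (a log2 ratio of 1 in size) were counted in each direction. Both log2 ratios were averaged in limma with an intercept fit and empirical Bayes moderation on 1 residual degree of freedom. Its p-values were adjusted by the Benjamini-Hochberg method over measured probes, with a threshold of 0.05. In this test the time points stood as replicates. The tests, the thresholds, the gene lists, the first rule for naming and 8 other ways of processing were chosen before the data were examined. The planned mean signal was not a column of the files, and the median signal was used in its place.

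The files did not pair probes with gene names, so the counts are of probes and not of genes. Of the probe identifiers, 0 equalled a symbol, gene number or accession of the reference gene table (assembly GRCh38). Running numbers of 102 probes happened to equal older gene names and were not used as names. A single further identifier equalled a synonym, and its probe was not measured. The PARP1 transcript and the medians of the 32 gene lists fixed beforehand (826 symbols) were therefore not analysed here. Control probes named for GAPDH and PGK1 were the exception. The first rule named, among genes past 2-fold the same way at both times, those with the highest and lowest mean log2 ratio, and passed over probes known by an identifier alone. As that left none, the rule was changed after the files were seen, and the 2 highest and 2 lowest probes were named by identifier. Classes of small and structural RNAs were read from the probe identifiers, a choice made after the files were seen. For each class other than the catalogue probes and the p series, the median log2 ratio was placed among 10000 random lists of equal size matched on intensity decile. The top decile is too wide to match the brightest probes, so no percentile is given for the class identified by an RNA number alone.

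The steps were tested on simulated data with the real green levels, a dye trend and 200 changed probes among 54402. For the test averaged over 48 h and 72 h, 84% of probes simulated 1.5-fold higher and 76% simulated 1.5-fold lower were called, and 92% and 100% of those simulated 2-fold higher and lower. Of all calls, 7.77% fell on unchanged probes. The simulated noise was independent between arrays (correlation 0.005 over unchanged probes) and held no dye bias of a probe shared by both. The real ratios correlated at 0.707, so this share does not carry over to the real test. Estimated ratios shrank towards 0, which the offset does most to dim probes, though recovery was not split by intensity. The median estimate was 0.58 for probes simulated 2-fold higher and -0.75 for those simulated 2-fold lower, and 8% and 12% of them passed 2-fold at both times. Of probes simulated 3-fold higher and lower, 76% and 76% passed 2-fold at both times, and 52% and 88% of those simulated 4-fold. In the simulation, counts past 2-fold therefore fell short, most of all for changes near 2-fold. Each simulated size and direction held 25 probes, so these shares are rough. Of the unchanged probes, 0 passed 2-fold at both times, but no shared dye bias was simulated that could add such calls. The real counts may thus be too low or too high. A list of 240 probes shifted by 0.15 gave medians of 0.10 at both times.

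The ways of processing fixed beforehand were no background correction, Feature Extraction's processed signals, median centring in place of loess, no filter on dim probes, a filter asking for both channels on both arrays, and the authors' value table. Of the same set, a median over the probes of a gene was not run, as no gene names were paired. Slide as a block was not run, as both arrays shared a slide. Those added after seeing the data were flagged spots kept, normexp without an offset, processed signals with the stricter filter, and leaving out the brightest probes.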

Results

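The transcriptome of A2058 human melanoma cells was measured after transfection with siRNA against PARP1, a nuclear enzyme that adds ADP-ribose chains to proteins at DNA breaks. Cells given a control siRNA served as the reference. Samples were taken at 48 h and 72 h, with 1 sample for each siRNA and time. The 4 groups therefore had no replicates, and the SDs given below are between spots of one probe on one array or between probes of one class. Of probes with an unflagged spot, 72.4% were well above background with PARP1 siRNA and 60.8% with control siRNA at 48 h. At 72 h the shares were 74.4% and 61.0%. PARP1 siRNA was always in Cy5 and control siRNA in Cy3. Negative control spots had median signals of 22 in Cy5 and 39 in Cy3 at 48 h, and 24 and 43 at 72 h. These shares therefore cannot be read as a difference between siRNAs. In all, 49238 of 75149 probes were measured on both arrays. The PARP1 transcript, the target of the siRNA, was not analysed here because the files do not pair probes with genes, so the knockdown was not checked.

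The first question was which transcripts differed between PARP1 siRNA and control siRNA at 48 h. Probe A_33_P3276703 had the highest ratio, 7.13-fold higher with PARP1 siRNA (log2 ratio 2.83, from 1 unflagged spot). Probe A_23_P130642, among the brightest on the array, was 2.60-fold higher (1.38 ± 0.05, SD, n = 2 spots), but below 2-fold with Feature Extraction's processed signals and with the authors' value table (0.89 in both). In the other direction, A_33_P3290338 was 3.12-fold lower (log2 ratio -1.64 ± 0.04, SD, n = 2 spots) and p4545 was 2.51-fold lower (-1.33 ± 0.11, SD, n = 2 spots). These probes were named for their mean over both times and were not all the most extreme at 48 h. Probe p19982 was lower still at 48 h (log2 ratio -1.81), but did not reach 2-fold at 72 h (-0.93). Among higher probes, A_21_P0010267 (log2 ratio 1.51) lay above A_23_P130642 at 48 h. Probes for small nucleolar and Cajal body RNAs, which guide the chemical modification of ribosomal and spliceosomal RNAs, had slightly higher ratios as a class. The 243 measured probes had a median log2 ratio of 0.15 (SD 0.20 between probes), above all 10000 random lists matched on intensity, and 180 of them lay above 0. The lists were not matched on dye response. With PARP1 siRNA in Cy5 on both arrays, a dye bias shared by the probes of a class would also shift its median.

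Transfer RNA probes, for the RNAs that carry amino acids to the ribosome, had a median of 0.03 over 33 measured probes at 48 h, at percentile 59.7 of matched lists. The sign turned under 4 other settings (-0.16 with the authors' value table), most of which rest on the same processed signals. Small nuclear RNA (snRNA) probes had a median of 0.01 over 86 probes, at percentile 41.0. Probes of the class named imsncRNA had a median of 0.01 over 745 probes, at percentile 55.7. Those named RNS had a median of -0.03 over 1038 probes, below all matched lists. With median centring in place of loess it was 0.16, but that setting moved the median of all measured probes to 0.14. No probe of these 5 classes reached 2-fold at 48 h. Over all probes, 37 were at least 2-fold higher and 10 at least 2-fold lower with PARP1 siRNA. Among the higher ones, 29 were Agilent catalogue probes, 4 belonged to the p series, 3 to its v4 version and 1 to ribosomal RNA. Higher probes made up 78.7% of these calls, against 89.4% with Feature Extraction's processed signals, 89.2% with the authors' value table and 99.4% with median centring. The share was lower, 57.7%, with processed signals and the stricter filter, and 68.75% without the brightest probes. Processed signals gave 1511 higher and 180 lower probes.

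PGK1 and GAPDH, enzymes of glycolysis, could be followed through named control probes. Of the lists fixed beforehand, these were the 2 genes with a name in the files. The 4 PGK1 probes well above background (human 3' and 5', mouse 5' and rat 5') had log2 ratios between 0.33 and 0.40 at both times. Over 7 processing settings they ranged from 0.29 to 0.93, with the highest value under median centring. With outlier-flagged spots kept, the human PGK1 3' probe stood at percentile 87.1 at 48 h and 91.6 at 72 h among probes within 0.5 log2 units of its intensity. On the human GAPDH probes, all spots but 2 at 48 h and all at 72 h carried outlier flags. With flagged spots kept, the human GAPDH 3' probe had log2 ratios of 0.48 ± 0.09 at 48 h and 0.35 ± 0.10 at 72 h (SD, n = 10 spots). The human GAPDH 5' probe had 0.75 ± 0.17 at 48 h and 0.85 ± 0.18 at 72 h (SD, n = 10 spots), against a median of 0.16 and 0.21 for probes of like intensity. The rat GAPDH 5' probe had 0.35 and 0.55. The dimmer mouse GAPDH 3' (0.01 and 0.05), mouse GAPDH 5' (0.03 and 0.06) and rat GAPDH 3' probes (0.11 and 0.15) had ratios nearer 0. As a sign of RNA integrity, the 3' minus 5' difference of the log2 ratio, also with flagged spots kept, was -0.27 and -0.50 for GAPDH and -0.08 and -0.03 for PGK1 at 48 h and 72 h.

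The probes named for their mean over both times were past 2-fold at 72 h as well. They were not all the most extreme at that time, as A_33_P3348061 (log2 ratio 1.99) lay above A_23_P130642. A_33_P3276703 was 5.11-fold higher with PARP1 siRNA (log2 ratio 2.35 ± 0.11, SD, n = 2 spots) and A_23_P130642 was 2.67-fold higher (1.42 ± 0.02, SD, n = 2 spots), again below 2-fold with processed signals and with the authors' value table (0.82 in both). A_33_P3290338 was 2.88-fold lower (-1.53, from 1 unflagged spot) and p4545 was 2.46-fold lower (-1.30 ± 0.10, SD, n = 3 spots). Small nucleolar and Cajal body RNA probes again had a raised median, 0.10 (SD 0.19 between probes), above all 10000 matched lists, with 178 of 243 above 0. The dyes were the same as at 48 h, so a dye bias of this class would recur. Transfer RNA probes were lower, with a median of -0.21 (SD 0.24 between probes), below all matched lists, and 30 of the 33 lay below 0. The median was -0.04 with median centring, where all measured probes had 0.12, and -0.36 with processed signals.

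The snRNA probes had a median of 0.02 at 72 h, at percentile 52.0, and imsncRNA probes 0.01, at percentile 40.6. RNS probes had a median of -0.04, below all matched lists. Their median was 0.13 with median centring, where all measured probes had 0.12. None of these 5 classes held a probe at or past 2-fold at 72 h. Over all probes, 48 were at least 2-fold higher and 8 at least 2-fold lower with PARP1 siRNA. The higher ones comprised 31 Agilent catalogue probes, 8 of the p series, 7 of its v4 version, 1 of ribosomal RNA and 1 identified by an RNA number alone. For 2 of the 48, a channel was not well above background on an array, so their folds are uncertain. Higher probes made up 85.7% of the calls, 64.4% with processed signals and the stricter filter, and 77.8% without the brightest probes. The share was 99.3% with median centring, which moved the median of all measured probes to 0.14 at 48 h and 0.12 at 72 h. Processed signals gave 871 higher and 91 lower probes.

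**Figure D1:**
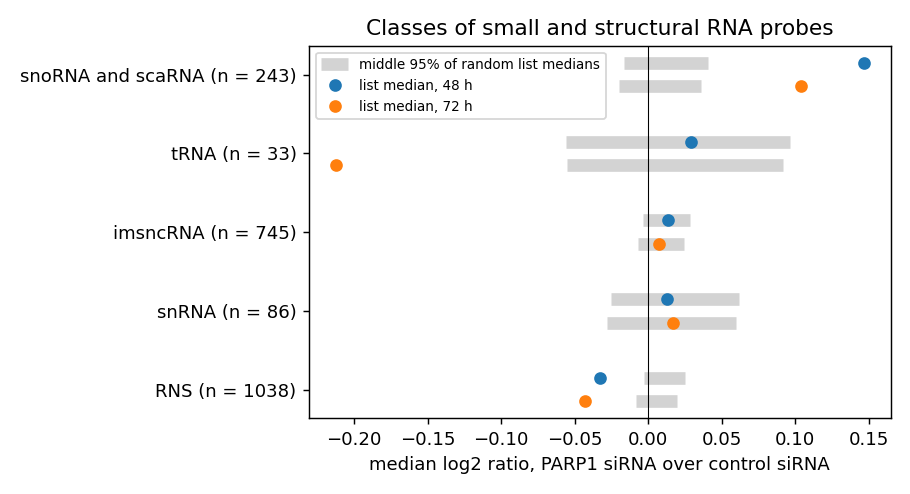
Median log2 ratio of PARP1 siRNA over control siRNA for 5 classes of RNA probes, at 48 h (blue) and 72 h (orange), with the number of measured probes in brackets and grey bars for the middle 95% of 10000 random list medians matched on intensity. Small nucleolar and Cajal body RNAs lay above the bars at both times (0.15 and 0.10), and transfer RNAs lay below at 72 h (-0.21). RNS probes lay below the bars at both times (-0.03 and -0.04). Under median centring the RNS medians were above 0 (0.16 and 0.13), as were those of all measured probes (0.14 and 0.12). PARP1 siRNA was in Cy5 at both times, so dye and siRNA were not separated.

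The next question was which differences were shared by both times. At or past 2-fold in the same direction, 20 probes were higher with PARP1 siRNA on both arrays and 3 were lower. Independent lists would share 0.036 and 0.0016 probes. PARP1 siRNA was in Cy5 on both arrays, so a dye bias of a probe would also be shared and raise the overlap. The 20 higher probes had log2 ratios from 1.02 to 2.83 at 48 h and from 1.01 to 2.35 at 72 h. The 3 lower ones lay between -1.64 and -1.16 at 48 h and between -1.53 and -1.01 at 72 h. No probe was 2-fold higher at one time and 2-fold lower at the other. Of the 20 higher probes, 14 were Agilent catalogue probes, 2 belonged to the p series, 3 to its v4 version and 1 to ribosomal RNA. A mean log2 intensity above 14 marked 13 of the 20, although only 130 of all measured probes were that bright, and their median log2 ratios were 0.47 and 0.50. With processed signals 336 probes were higher and 18 lower at both times, including 6 of the 20 and all 3 lower ones. Of the probes this bright, 0 were 2-fold higher at both times with processed signals or with the authors' value table.

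**Figure D2:**
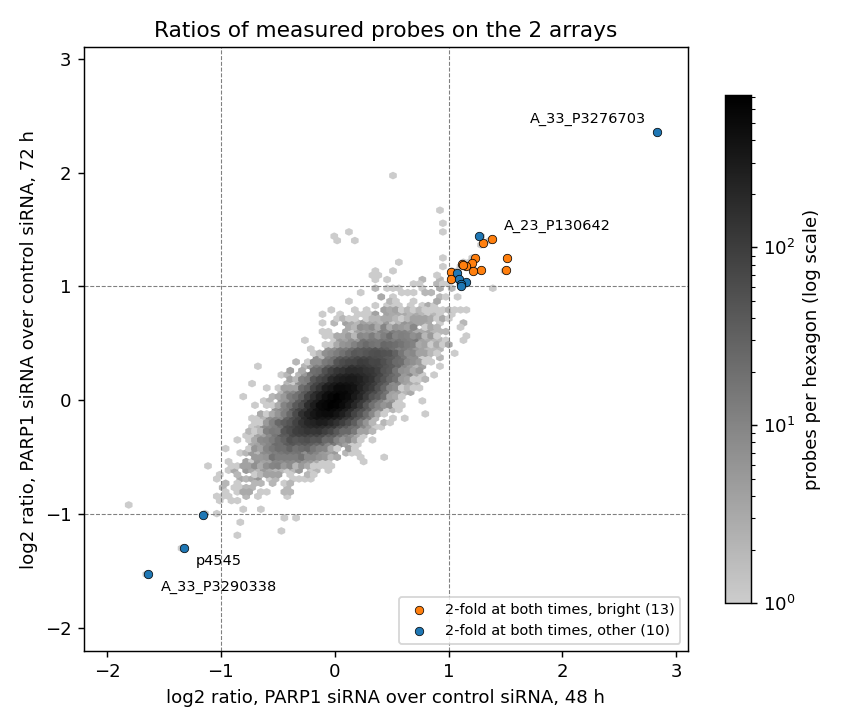
Log2 ratio of PARP1 siRNA over control siRNA at 48 h (x axis) and 72 h (y axis) for 49238 measured probes, shaded by the number of probes, with dashed lines at 2-fold. Coloured points are the 20 probes higher and 3 lower at both times; orange marks the 13 with a mean log2 intensity above 14.

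**Figure D3:**
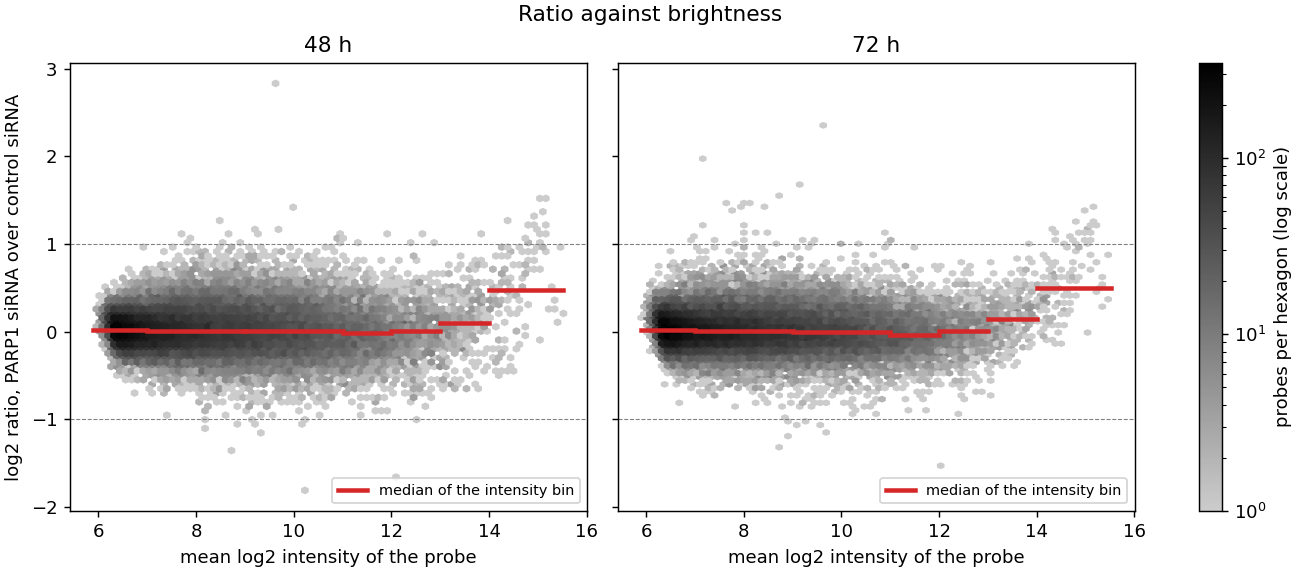
Log2 ratio of PARP1 siRNA over control siRNA (y axis) against mean log2 intensity (x axis) for 49238 measured probes at 48 h (left) and 72 h (right), with red lines at the median of each intensity bin and dashed lines at 2-fold. The median stays near 0 up to an intensity of 13 and reaches 0.47 at 48 h and 0.50 at 72 h above 14.

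Averaged over both times, the named probes passed the limma test, but they had been picked by the mean that it tests. The mean log2 ratio was 2.59 for A_33_P3276703 (adjusted p = 5.84e-21), 1.40 for A_23_P130642 (adjusted p = 5.5e-15), -1.58 for A_33_P3290338 (adjusted p = 2.34e-16) and -1.31 for p4545 (adjusted p = 1.45e-14), each from 2 arrays of the same direction. Of the 243 small nucleolar and Cajal body RNA probes, 84 were called higher and 6 lower. Transfer RNA probes gave 0 higher and 8 lower of 33, snRNA probes 5 and 6 of 86, imsncRNA probes 120 and 62 of 745, and RNS probes 49 and 111 of 1038. All 23 probes past 2-fold at both times were among the calls, which nearly had to follow from how they were picked. The moderation carried 31.7 prior degrees of freedom at a prior SD of 0.106. The adjusted p-values weigh the spread between 2 arrays with the same dyes, not variation between transfections.

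Over all probes, limma with Benjamini-Hochberg adjustment called 7353 higher and 4922 lower with PARP1 siRNA, 24.9% of those measured. Of the called probes 95.5% had a mean ratio under 1.5-fold, and their median size was 0.28 log2 units. Higher probes made up 59.9% of the calls, 88.8% with median centring, 70.3% without an offset, and 52.4% with processed signals and the stricter filter. At an unadjusted p under 0.05, 10190 were higher and 7498 lower. Across probes, which are not independent replicates, the log2 ratios of both arrays correlated at r = 0.707 (Spearman 0.650). A dye bias of a probe that was the same on both arrays would be counted as a difference by this test, since PARP1 siRNA was in Cy5 each time. With processed signals the same test called 0 probes either way, against 7816 higher and 5358 lower at an unadjusted p under 0.05.

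The difference of the log2 ratios between times asked whether the response changed from 48 h to 72 h, and here a constant dye bias cancels. For 5 probes the ratio was at least 2-fold higher at 72 h than at 48 h, and for 0 it was at least 2-fold lower. These 5 comprised 2 of the p series, 2 of its v4 version and 1 Agilent catalogue probe. Their log2 ratios lay between 0.00 and 0.52 at 48 h and between 1.39 and 1.99 at 72 h. The level in cells given PARP1 siRNA was higher at 72 h than at 48 h by 1.59 to 1.77 log2 units for these probes, and the level in control cells by 0.13 to 0.41. For 1 of the 5 a channel was not well above background on an array. Transfer RNA probes had a median difference of -0.24, below all 10000 matched lists, and 27 of 33 had a lower ratio at 72 h. Small nucleolar and Cajal body RNA probes had a median difference of -0.02, at percentile 3.99. None of these differences could be tested with 1 array per time, and processed signals gave 423 probes higher and 702 lower at 72 h.

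Within each siRNA, levels at 72 h were compared with those at 48 h. In control cells 23 probes were at least 2-fold higher and 28 at least 2-fold lower at 72 h. In cells given PARP1 siRNA the counts were 58 and 48. Both siRNAs shared 20 of the higher and 19 of the lower probes, where independent lists would share 0.027 of each. The shared higher probes changed by 1.005 to 2.09 log2 units in control cells and by 1.02 to 2.17 with PARP1 siRNA. Transfer RNA probes were higher at 72 h in control cells, by a median of 0.25 (above all matched lists), and by 0.03 with PARP1 siRNA (percentile 88.9). RNS and imsncRNA probes had medians of 0.04 under both siRNAs, each above all lists. Small nucleolar and Cajal body RNA probes had 0.03 in control cells (percentile 98.6) and 0.02 with PARP1 siRNA (96.9), and snRNA probes 0.01 (78.55) and 0.05 (99.2). The 6 ribosomal RNA probes had -0.10 (13.8) and -0.12 (6.83), and the 5 vault RNA, ribozyme and SRP RNA probes 0.06 (78.8) and -0.13 (4.85). Across probes both time changes correlated at r = 0.745, but time and array were confounded, so part of this can come from the arrays. Without background correction the counts were 53 higher and 54 lower in control cells and 89 and 82 with PARP1 siRNA. Processed signals reversed the order of the siRNAs, with 829 and 677 in control cells and 406 and 427 with PARP1 siRNA. The authors' value table, which closely follows those signals and is no separate check, gave 897 and 702 against 524 and 473. Normexp without an offset also reversed the order, with 221 and 207 against 203 and 167.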

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

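All tests of the spike-ins in this part, and the comparison of class medians between times, were chosen after the results were seen.

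Signal in control spots outside the comparisons stood out. The 10 E1A spike-in RNAs were brighter in Cy5, with median log2 ratios of 1.19 at 48 h and 1.004 at 72 h after loess on the other probes. They ranged from -0.68 to 4.44 at 48 h and from -0.52 to 4.45 at 72 h, and 9 of the 10 lay above 0 at both times. A spike-in's ratio differed by at most 0.27 between arrays. Designed ratios of the spike-in mixes as the sole reason are argued against by the scanner files, which give the intercept of observed on expected log10 ratio as 0.489 at 48 h and 0.474 at 72 h, where the mixes alone would give about 0. What stays open is unequal spike-in or RNA amounts between the labelled samples, which may shift all spike-ins together, as the median of 1.004 at 72 h would need. Observed and expected ratios correlated at 0.950 at 48 h and 0.922 at 72 h, so the spread between spike-ins in part followed the mixes. Loess had centred other probes of like intensity near 0, with medians of 0.008 and 0.004 between log2 intensities of 7 and 9, and 0.006 and -0.008 between 9 and 11. Unequal amounts cannot be told apart from a dye effect particular to the spike-ins, because PARP1 siRNA was in Cy5 on both arrays. No biological explanation was tested.

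Of 12 probes for ERCC spike-ins, 2 were well above background in both channels of both arrays and 9 in none. The log2 ratios of these 2 lay near 0, -0.08 and -0.07 at 48 h and -0.05 and -0.01 at 72 h, unlike those of E1A. Probes for transfer RNAs had medians of opposite sign at both times, 0.03 and -0.21, with a median difference of -0.24. The 48 h median turned negative with processed signals (-0.01), the authors' value table (-0.16), flagged spots kept (-0.12) and processed signals under the stricter filter (-0.06), so the opposite sign depended on the processing. All of these but flagged spots kept rest on the same processed signals. Those for vault RNA, ribozyme and SRP RNA, 5 in all, had 0.23 and -0.02, with a median difference of -0.14. Neither difference between times was tested, since each time had 1 array. Among random lists of like intensity on these arrays, the differences stood at percentiles 0 and 3.87, which describes the probes and not the variation between samples.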

How the results depend on the processing

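The results under flagged spots kept, no normexp offset, processed signals with the stricter filter, and without the brightest probes come from tests chosen after seeing the data; the other alternatives were planned. Values are given as higher and then lower. No filter on dim probes, and the filter for both channels on both arrays, moved none of the 15 counts and correlations by over 1.5 times.

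With processed signals the counts were 1511 and 180 at 48 h, 871 and 91 at 72 h, 336 and 18 at both times, 0 and 0 in the limma test (7816 and 5358 at an unadjusted p under 0.05), 423 and 702 for the difference between times, 829 and 677 for the time change in control cells, and 406 and 427 with PARP1 siRNA. The authors' value table gave 1534 and 186, 878 and 94, 341 and 19, 0 and 0 (9576 and 5836 at an unadjusted p under 0.05), 425 and 703, 897 and 702, and 524 and 473 in that order. Processed signals with the stricter filter gave 164 and 120, 103 and 57, 33 and 16, 2688 and 2440, 65 and 65, 205 and 163, and 286 and 241. Normexp without an offset gave 341 and 52, 247 and 18, 77 and 6, 2641 and 1115, 86 and 99, 221 and 207, and 203 and 167.

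Median centring gave 480 and 3 at 48 h, 277 and 2 at 72 h, 213 higher at both times, 19624 and 2483 in the limma test, and 1 probe with a lower ratio at 72 h. Without background correction there were 19 lower at 48 h, 2 with a lower ratio at 72 h, 53 and 54 for the time change in control cells, and 89 and 82 with PARP1 siRNA. With flagged spots kept there were 15 lower at 72 h, 5 with a lower ratio at 72 h, and 59 higher at 72 h in control cells. Without the brightest probes there were 22 higher at 48 h, 28 at 72 h and 7 at both times, which follows from leaving out probes that were among those counted. For the other settings the cause was not tested.

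The correlation between arrays stayed between 0.590 (processed signals) and 0.820 (median centring). Under the 10 alternatives, A_33_P3276703 ranged from 2.34 to 3.26, A_33_P3290338 from -1.83 to -1.05 and p4545 from -1.58 to -1.05 over both times. A_23_P130642, which has no value without the brightest probes, ranged from 0.82 to 2.26 and was below 2-fold with processed signals. The median of small nucleolar and Cajal body RNA probes ranged from 0.12 to 0.28 at 48 h and from 0.09 to 0.22 at 72 h. That of transfer RNA probes ranged from -0.16 to 0.13 at 48 h and from -0.39 to -0.04 at 72 h. For both classes the upper ends came from median centring. That setting put the median of all measured probes at 0.14 at 48 h and 0.12 at 72 h.

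No paired analysis was possible because each group had 1 sample; the averaged test already takes its ratios within arrays. The planned median over the probes of a gene, the PARP1 ratio and the medians of gene lists were not run without gene names, and slide as a block was not run because both arrays shared a slide. Not measured on both arrays, for low signal or outlier flags, were 25911 of 75149 probes.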

Other observations

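The tests of bright probes, of noise and of dye bias were chosen after the results were seen. The test that subtracts an intensity trend from the correlation was chosen before its result.

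The 11 probes identified by an RNA number alone had a median log2 ratio of 0.25 at 48 h and 0.36 at 72 h with PARP1 siRNA over control siRNA, at a median log2 intensity of 14.2, and 10 of the 11 lay above 0 at both times. All probes above 14 had medians of 0.47 and 0.50, and those between 13 and 14 had 0.10 and 0.14, so the ratios of this class were not separated from its brightness. The 6 ribosomal RNA probes had medians of 0.11 and 0.05, at percentiles 86.7 and 65.4. The ribosomal RNA probes were mostly dim, with a median log2 intensity of 7.13, and the single one past 2-fold was among the brightest probes described next.

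Probes with a mean log2 intensity above 14 were higher with PARP1 siRNA as a set: of these 130 probes, 105 lay above 0 at both times and 13 were at least 2-fold higher at both. After subtracting the median ratio of the 51 nearest probes in intensity, 0 of the 13 stayed 2-fold higher at both times, and the median of their mean log2 ratios was 0.37, from 1.21 before. This does not decide on a dye response at the top of the intensity range left by the normalization, since the raised median of the bright set alone ends all 13 calls and a real rise of the whole set would be removed alike. Feature Extraction's own normalization gave the bright probes medians of 0.15 and 0.08. Both this dye response and more of these RNAs in cells given PARP1 siRNA stay open, since the median of 0.47 at 48 h would look alike and dye and siRNA cannot be told apart.

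The log2 ratios of both arrays correlated across probes at 0.707, where independent measurement noise would give a value near 0. An intensity trend shared by the arrays as the whole reason is argued against by a correlation of 0.686 after the same subtraction. A probe-specific dye bias stays open, as may a response to PARP1 siRNA: the 4 PGK1 probes well above background scattered by an SD of 0.033 in their mean log2 ratio, with flagged spots kept. On the same basis the bright GAPDH probes stood further apart, with human 3' at 0.48 and 0.35, human 5' at 0.75 and 0.85, and rat 5' at 0.35 and 0.55. These cover 2 genes. The mouse and rat probes were read with human RNA, and the PGK1 probes are mostly 5' probes, so they may not be unrelated sequences. Arrays with the dyes swapped would be needed.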
